A study of Mus musculus with 18 samples.

How the data were processed

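RNA-seq libraries were made from sorted mouse regulatory T cells. The labels give 3 genotypes, written here as +/+, fl/+ and fl/fl. They give 2 states, resting and effector, and batch numbers 1 to 3, which makes 18 libraries in 6 groups of 3. Sex, age and the markers of the sorting gates are not given in the sources used here. Cells were sorted into TCL buffer with 1% beta-mercaptoethanol and frozen, per the labels. The labels do not say that replicates are separate animals, so each p-value below measures the spread between these samples.

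The submitters' processing notes name bcl2fastq 2.17.1.14, STAR 2.6.0 and RSEM 1.2.8 with genome build mm10. The annotation, the strand setting and any filter are not given in the sources used here. The deposited table of expected counts, in which the authors give RSEM output per gene symbol and library, was the input of every main test. The deposited FPKM table, also from the authors, was used only in alternatives. Of the nonzero expected counts, 29.4% were not whole numbers, because RSEM divides reads that fit several genes, and all were rounded before fitting.

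The table holds 23420 genes. Library totals ran from 1658073 to 5756903 expected counts with a median of 3154386.5, and 9104 to 10854 genes had at least 10 counts in a library. The ribosomal RNA gene Rn45s took 10.9 to 16.4% of each library. Within groups the Pearson correlation of log2 CPM was 0.953 to 0.976, and the chi-square per gene between replicates was 3.52 to 7.03, where counting error alone gives a value near 1. Groups with no count were fitted without a floor. The floor named below is only a level of about 3 counts, and it covers counting error only. The common dispersion was 0.0215. No share was estimated from reads at a site, so no binomial interval was needed.

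Counts were analysed in R 4.3.3 with edgeR 4.0.16. Scaling was by TMM (factors 0.9394 to 1.063), genes were filtered with filterByExpr by group, which kept 10630, and a model with 6 group means was fitted to all 18 libraries. Contrasts were tested with the edgeR quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no limit on the fold. Fold changes are log2 values with the standard error of the fit. Group levels are mean CPM with SD over 3 libraries. The contrasts were effector against resting in each genotype, fl/fl against +/+, fl/+ against +/+ and fl/fl against fl/+ in each state, and an interaction for fl/+ and for fl/fl, which is the change between states in that genotype less the change in +/+.

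A set of 28 gene lists was fixed in advance from general knowledge of T cells. They hold 460 distinct genes, of which 60 are in more than 1 list, 15 are absent from the table and 80 are in the table but too low to test. Lists with at least 5 tested genes, 22 in all, were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists of a contrast. Each call was also tested with the correlation estimated from the residuals and with fry. A count "over the list alone" adjusts p-values only over the members of that list. An effector signature was taken from fl/+: the 200 genes with the lowest p-values among those called higher between states, and 200 among those called lower. It was tested in fl/fl against +/+, and the one from +/+ in fl/fl against fl/+, so that no library was used on both sides. These 4 tests per signature were adjusted together.

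Genes were named by a rule with 3 parts: members of the CBM complex, such as Bcl10 and Malt1; the 10 highest and the 10 lowest fold changes among called genes with a mean of at least 5 CPM over the 18 libraries and no overlap between the groups, which happens by chance in 10% of genes at 3 against 3; and members of the lists. The second part leaves out predicted gene models, microRNA, small nucleolar RNA and receptor segments. This removed 56, 59 and 19 genes from the state contrasts of +/+, fl/+ and fl/fl, 4, 3 and 1 from the resting contrasts in the order given above, and 6, 0 and 2 from the effector ones. Grouping, contrasts, lists, the naming rule, the threshold and a first set of alternatives were chosen before the data were examined.

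Because both genotype contrasts against +/+ share the +/+ libraries, 50 simulations with no genotype effect gave the correlation and covariance expected from sharing alone. In them all 9 libraries of a state, +/+ included, were drawn around one mean per gene. The plan had drawn only the other genotypes, which leaves out the error of the +/+ libraries, and this was changed after seeing the data. The number that the labels call batch was checked for pairing in the residuals of the 6-group model. The 9 pairs of one genotype and number, resting with effector, had a mean correlation of 0.25 (0.16 to 0.41). Same number and other genotype gave 0.08 over 36 pairs (-0.09 to 0.34), and 15 of those pairs exceeded 0.1. Different number and same genotype gave -0.12 over 18 pairs, and different in both gave -0.04 over 72. Deviations from a group mean sum to 0, so values below 0 for pairs of different number are partly forced. The main model leaves the number out, because no method text says that the authors used it. It therefore ignores the pairing of resting and effector libraries seen here. The number was used as a block in alternatives.

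The alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, no filter beyond 1 count, a filter of 5 CPM in 3 libraries, the batch number as a block (the replicate block), a fit to only the groups compared, each library left out in turn, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), signatures of 100 and 400 genes, and the set tests named above. Chosen after seeing the data were leaving out every library of one number, leaving out genes that differ between numbers, leaving out Rn45s, a block of genotype and number together (the block within genotype), a signature without proliferation members, and leaving out genes whose longest protein-coding transcript in GENCODE M21 holds a stretch of 100 bases with at least 80% G and C. In each group contrast, the 10 ways to divide the 6 libraries 3 against 3 were also fitted, and for the interactions 49 random splits beside the real division.

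The procedure was tested on simulated data built from the mean CPM of each gene over all libraries and its fitted dispersion. In them 200 genes were changed in the fl/fl effector group alone. In fl/fl against +/+ effector cells edgeR recovered 31.3% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 95.5% of those changed 4-fold, with 2 false calls. In the interaction it recovered 2.99%, 43.3% and 86.4%, with 1 false call. DESeq2 recovered 34.3%, 70.1% and 98.5% in the first contrast, with 6 false calls. The unchanged fl/+ against +/+ contrast gave 0 false calls. Of 100 random lists of 20 genes, camera put 0 under an unadjusted 0.05, camera with an estimated correlation 0 and fry 6. Each gene was drawn on its own, so these lists hold no correlation between genes. They cannot show whether the preset correlation is high enough for the real lists.

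The completeness of the deletion was not measured, and results for some of the named genes are not reported here. Reads were not available, so junctions, strand and unaligned sequence were left out.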

Results

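Effector and resting regulatory T cells differed most. In a principal component analysis of the 1000 most variable genes, the first axis held 56.1% of the variance and set effector apart from resting libraries, and the second held 9.1%. Groups were uneven inside. On the first axis fl/fl resting replicate 1 was at -12.6 and the other resting libraries at -37.3 to -22.3, and on the second axis +/+ effector replicates 1 and 2 were at -19.6 and -23 and replicate 3 at 3.1. Between states 1700 genes were called in +/+, 1732 in fl/+ and 674 in fl/fl. Between fl/fl and +/+, 299 genes were called in effector cells and 74 in resting cells. Between fl/+ and +/+ the counts were 1 and 9, and 175 genes differed between replicate numbers. Xist, which is transcribed from the silent X chromosome, was at a mean of 749 to 966 CPM in every group.

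**Figure D1:**
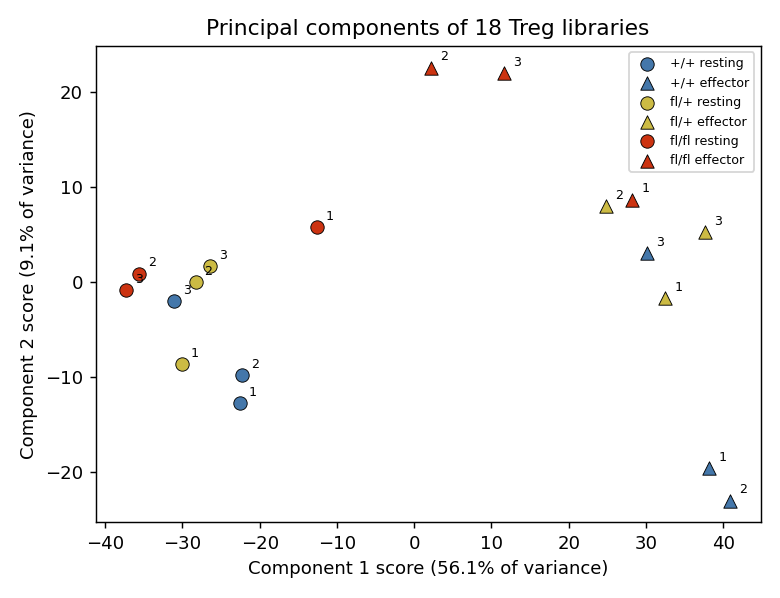
Libraries on the first (56.1% of variance, horizontal) and second (9.1%, vertical) principal components, coloured by genotype, with a shape for each state and the replicate number beside each point. Of the fl/fl effector libraries, replicates 2 and 3 lie at 2.2 and 11.6 on the first axis and replicate 1 at 28.2, beside the fl/+ effector libraries.

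Malt1, the protease of the CBM complex, rose from resting to effector cells in +/+ by 1.33 (SE 0.22, adjusted p = 0.000278, 169 against 67.9 CPM) and in fl/+ by 0.98 (SE 0.21, adjusted p = 0.00314, 141 against 71.5 CPM). In fl/fl the Malt1 change was 0.36 (SE 0.22, adjusted p = 0.397, 105 against 82.1 CPM). Its difference between fl/fl and +/+ effector cells was -0.68 (SE 0.21, adjusted p = 0.0852). Bcl10, the adaptor that binds Malt1, was called in no contrast. Its change between states was 0.20 in +/+ (SE 0.16, adjusted p = 0.451, 75.8 against 65.9 CPM), and in effector cells fl/fl less +/+ it was -0.12 (adjusted p = 0.779).

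In +/+ effector against resting cells Il10, a suppressive cytokine, rose by 7.73 (SE 0.90, adjusted p = 1.53e-05), from 0.0846 to 31.3 CPM (SD 10.2, n = 3). Gzmb, a cytotoxic protease, rose by 6.77 (SE 0.93, adjusted p = 8.75e-05), from 0.169 to 28.1 CPM. Among the other 10 highest were Asb2 (8.44, SE 1.28), Arnt2 (6.28, SE 0.81), Ccr2 (6.24, SE 0.76), Lilrb4 (6.12, SE 0.76) and Tox2 (5.67, SE 0.74). Ces2c (33.4 CPM) and Ptpn5 (14.6 CPM) had no count in resting cells. The lowest included Ggt5 (-3.13), Dapk1 (-3.02), Adcy6 (-2.89, SE 0.36, adjusted p = 2.41e-05), Dapl1 (-2.84, SE 0.60), Cnn3 (-2.83, SE 0.36), the lymphocyte antigen Ly6c1 (-2.73, SE 0.65) and Igfbp4 (-2.47, SE 0.45, 110 against 616 CPM).

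Lists of function and activation moved with the effector state in +/+. Of 17 genes for suppression, 15 rose, 1 fell and 1 was not called. Their median log2 change was 2.82 (camera adjusted p = 7.56e-20, and adjusted p = 0.0168 with an estimated correlation). They include the inhibitory receptors Ctla4 (1.53, SE 0.22, 407 against 140 CPM), Tigit (5.28, SE 0.71) and Lag3 (4.68, SE 0.48, 366 against 13.4 CPM). Of 27 effector markers 23 rose and 4 were not called (24 over the list alone; median 2.47, adjusted p = 7.22e-29, 0.0168 with an estimated correlation). Examples are the costimulatory receptor Icos (2.82, SE 0.33, 509 against 71.7 CPM), the repressor Prdm1 (2.95, SE 0.37), Batf (1.57, SE 0.16) and Maf (3.89, SE 0.50). Klrg1 was at 3.49 (SE 1.2, adjusted p = 0.0542, and 0.0128 with the replicate block).

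Markers of resting cells went the other way in +/+. Of 20 genes 14 fell and 6 were not called (15 over the list alone; median -1.32, adjusted p = 3.01e-18, 0.0168 with an estimated correlation). The transcription factors Lef1 (-1.48, SE 0.18, 156 against 438 CPM), Satb1 (-1.97, SE 0.23, 57.6 against 227 CPM) and Bach2 (-1.22, SE 0.16) fell. The chemokine receptor Ccr7 fell by 0.82 (SE 0.17), and Tcf7 was at -0.28 (adjusted p = 0.167). Of 19 genes of Treg identity 11 rose and 8 were not called (list alone 11 higher, 2 lower; median 0.63, adjusted p = 4.82e-06, and adjusted p = 0.0858 with an estimated correlation). Ikzf2 rose by 0.58 (SE 0.17, adjusted p = 0.0223) and Nrp1 by 0.91 (SE 0.22). Foxp3, the lineage factor, was at 0.10 (SE 0.24, adjusted p = 0.842, 325 against 305 CPM), and Il2ra at -0.10 (adjusted p = 0.708).

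Programmes of helper subsets rose in +/+ effector cells. For Th17, 7 of 9 genes rose (median 3.93, adjusted p = 1.02e-09, 0.0168 with an estimated correlation), with Ccr6 at 3.21 (SE 0.43) and Ahr at 3.93 (SE 0.51). For Th2, 6 of 8 rose and 1 fell (median 2.67, adjusted p = 8.24e-07, 0.0168 with an estimated correlation), with Ccr4 at 3.44 (SE 0.30, 116 against 10.2 CPM) and Il1rl1 at 2.43 (SE 0.61), while Gata3 was at 0.17 (adjusted p = 0.397). For Tfh, 9 of 10 rose (median 2.47, adjusted p = 4.55e-11, 0.0262 with an estimated correlation), with Pdcd1 at 2.42 (SE 0.37) and Angptl2 at 4.32 (SE 0.43). For Th1, 9 of 16 rose and 7 were not called (13 over the list alone; median 2.22, adjusted p = 1.91e-09, and adjusted p = 0.0567 with an estimated correlation), with Cxcr3 at 5.36 (SE 0.64, 115 against 2.61 CPM) and Tbx21 at 3.62 (SE 0.80). Of 27 migration genes 17 rose and 4 fell (list alone 17 and 6; median 1.72, adjusted p = 3.18e-08, 0.0318 with an estimated correlation). Itgae (3.88, SE 0.66) and Cxcr6 (4.29, SE 0.76) rose, and S1pr1, needed to leave lymph nodes, fell by 2.01 (SE 0.29).

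Among pathway lists in +/+, 13 of 29 NF-kB targets rose, 3 fell and 13 were not called (list alone 14 and 4; median 0.40, adjusted p = 0.000187, and adjusted p = 0.172 with an estimated correlation). Tnfrsf1b (1.75, SE 0.22) and Relb (1.06, SE 0.17) rose, and Rel was at -0.42 (adjusted p = 0.0925, and 0.0253 with the replicate block). Of 28 proliferation genes 17 rose (21 over the list alone; median 1.36, adjusted p = 1.02e-09, and adjusted p = 0.199 with an estimated correlation), with Mki67 at 2.25 (SE 0.43, 41.5 against 8.7 CPM) and Birc5 at 1.25 (SE 0.36). Of 21 glycolysis genes 6 rose (8 over the list alone; median 0.29, adjusted p = 0.00726, and adjusted p = 0.345 with an estimated correlation), and the list was not called without +/+ effector replicate 3 (0.17, adjusted p = 0.0726). Pkm rose by 0.39 (SE 0.09), and Ldha was at -0.18 (adjusted p = 0.251).

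The lists that did not pass in +/+ were CBM signalling (1 of 14 higher, 3 lower; median -0.09, adjusted p = 0.207), early receptor response (3 of 17 higher, 1 lower; 0.25, adjusted p = 0.235), interferon response (1 of 26 higher; -0.22, adjusted p = 0.14), apoptosis (5 of 23 higher, 3 lower; -0.02, adjusted p = 0.566), oxidative phosphorylation (0 of 30; -0.07, adjusted p = 0.17), cholesterol synthesis (1 of 19 higher, 1 lower; -0.21, adjusted p = 0.18) and IL-2/STAT5 (2 of 19 higher, 3 lower; -0.10, adjusted p = 0.44). Within them Prkcq fell by 0.57 (SE 0.10), Egr2 rose by 0.97 (SE 0.18), Hmgcs1 fell by 0.66 (SE 0.20) and Bcl2 fell by 1.42 (SE 0.20). The dissociation list had 1 of 21 genes lower (0.06, adjusted p = 0.945).

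Markers of other cells were measured beside these groups. B cell genes had a median change of -1.90 in +/+ (0 of 8 called, adjusted p = 0.734), and their summed level was 135 CPM (SD 173, 28.9 to 335) in +/+ resting cells and 86.8 (SD 20.1) in effector cells. Markers of conventional CD4 cells summed to 2180 CPM in resting and 1160 in effector +/+ cells, with 3 of 7 higher and 3 lower (median -0.65, adjusted p = 0.463). Lists with few tested genes were not tested as sets: plasma cell (Prdm1 rose, 1 of 3), myeloid (Cst3 rose by 0.53, 1 of 4), dendritic (0 of 3; median 0.77) and CD8 or NK (1 of 4 higher, 2 lower; Prf1 -2.22, Nkg7 2.30). No red cell gene was tested, and Xist, the tested member of the sex-linked list, was at 0.21 (adjusted p = 0.187). Over the whole contrast 1009 genes rose and 691 fell in +/+, 748 of them more than 2-fold. With log2(FPKM + 1) as the unit the split was 1330 higher and 459 lower.

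In fl/+ effector against resting cells Il1r2, a decoy receptor for interleukin 1, rose by 6.19 (SE 0.62, adjusted p = 8.09e-06, 50.3 against 0.804 CPM), and Il10 rose by 6.13 (SE 1.00, adjusted p = 0.00027, 10.3 against 0.131 CPM). Lilrb4 (6.67, SE 0.84), Tox2 (6.54, SE 0.85), Asb2 (6.25, SE 1.19) and Ccr2 (6.20, SE 0.80) were also among the highest. Gzmb was at 8.59 CPM and Ces2c at 14.7 CPM, with no count of either in resting cells. Among the lowest were Ly6c1 (-2.81, SE 0.63), Emid1 (-2.77), Dapk1 (-2.53), the pore protein Prf1 (-2.38, SE 0.38), the antiviral gene Oas2 (-2.27, SE 0.52, 8.8 against 41.4 CPM), the quiescence factor Klf2 (-2.13, SE 0.34) and Adcy6 (-2.13, SE 0.30).

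Most lists moved in fl/+ as they had in +/+, each described here in fl/+ itself. Of 17 suppression genes 14 rose and 1 fell (median 2.15, adjusted p = 1.55e-15), with Ctla4 at 1.5 (SE 0.23) and Lag3 at 4.39 (SE 0.49). Of 27 effector markers 23 rose (26 over the list alone; 2.06, adjusted p = 1.88e-25), with Icos at 2.45 (SE 0.32) and Prdm1 at 1.91 (SE 0.37). Of 20 resting markers 13 fell (16 over the list alone; -0.99, adjusted p = 2.7e-14), with Lef1 at -1.35 (SE 0.18) and Satb1 at -1.70 (SE 0.22). Each of these had an adjusted p of 0.0387 with an estimated correlation. Th2 (5 of 8 higher, 1 lower; 2.14, adjusted p = 1.53e-05) and Tfh (9 of 10 higher; 2.52, adjusted p = 2.21e-10) had the same estimated value. For Th17 it was 0.0389 (7 of 9 higher; 3.60, adjusted p = 3.21e-07), with Ccr6 at 3.60 (SE 0.48). For migration it was 0.0443 (16 of 27 higher, 5 lower; 1.95, adjusted p = 2.78e-07). Ccr4 rose by 4.45 (SE 0.34, adjusted p = 3.39e-07).

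Other lists of fl/+ passed at the preset correlation alone. Of 28 proliferation genes 24 rose (28 over the list alone; 2.03, adjusted p = 2.63e-19, and adjusted p = 0.0565 with an estimated correlation), with Mki67 at 2.96 (SE 0.43, 54.2 against 7.19 CPM) and Top2a at 2.59 (SE 0.43). Treg identity had 11 of 19 higher (0.73, adjusted p = 3.3e-06, and adjusted p = 0.08 with an estimated correlation), with Ikzf2 at 0.73 (SE 0.17) and Foxp3 at -0.27 (adjusted p = 0.51). Th1 had 7 of 16 higher (9 over the list alone; 1.76, adjusted p = 3.28e-06, and adjusted p = 0.111 with an estimated correlation). NF-kB targets had 11 of 29 higher and 3 lower (list alone 12 and 6; 0.32, adjusted p = 0.00409, and adjusted p = 0.274 with an estimated correlation), with Tnfrsf9 at 0.96 (SE 0.21) and Nfkb2 at 0.72 (SE 0.16). Glycolysis had 8 of 21 higher (9 and 1 over the list alone; 0.34, adjusted p = 0.00262, and adjusted p = 0.274 with an estimated correlation), with Hk2 at 2.93 (SE 0.61).

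CBM signalling was lower in fl/+ effector cells, with 4 of 14 genes lower and 1 higher (-0.15, adjusted p = 0.0122, and adjusted p = 0.0845 with an estimated correlation). Prkcq (-0.63, SE 0.10, adjusted p = 0.000175) was among them. In the interferon list 6 of 26 genes fell and 1 rose (9 and 1 over the list alone; -0.41, adjusted p = 0.00408, and adjusted p = 0.536 with an estimated correlation), with Ifit1 at -1.03 (SE 0.33) and Rtp4 at -0.73 (SE 0.23). Oasl2 was at -1.02 (adjusted p = 0.0727, and 0.0458 with the replicate block). The lists that did not pass were early receptor response (0.02, adjusted p = 0.524), apoptosis (-0.09, adjusted p = 0.624), oxidative phosphorylation (0.04, adjusted p = 0.687), cholesterol synthesis (-0.04, adjusted p = 0.624), IL-2/STAT5 (-0.14, adjusted p = 0.417), dissociation (-0.05, adjusted p = 0.553), B cells (0.32, adjusted p = 0.524) and conventional CD4 cells (-0.43, adjusted p = 0.862). Of the 1732 genes 1033 rose and 699 fell, 803 of them more than 2-fold. On log2(FPKM + 1) the split was 1233 and 401. The count was 1114 without fl/+ resting replicate 1 and 1092 without fl/+ effector replicate 3.

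In fl/fl cells, genes of the cell cycle stood among the highest changes between states. Aurkb, a mitotic kinase, rose by 3.73 (SE 0.58, adjusted p = 0.00073, 22.1 against 1.55 CPM), Bub1 by 3.66 (SE 0.71) and the cyclin Ccna2 by 3.60 (SE 0.66, 59.5 against 4.63 CPM). Lilrb4 (4.30, SE 1.05) and the homing receptor Gpr15 (4.25, SE 0.82) also rose, with Wnt10a (3.69), Zan (3.66), Chst2 (3.60) and Fam160a1 (3.56). Among the lowest were Zfp318 (-1.22, SE 0.29), Atp1b1 (-1.06, SE 0.19), Pde4d (-1.06, SE 0.29), Tec (-1.05, SE 0.23) and Satb1 (-0.83, SE 0.21, 140 against 247 CPM). Il10 was at 1.44 (SE 1.01, adjusted p = 0.484), and Gzmb at 2.32 (adjusted p = 0.0754).

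Proliferation was the list of fl/fl that kept its call with an estimated correlation. Of 28 genes 27 rose (28 over the list alone; median 2.45, adjusted p = 5.48e-53, 0.0143 with an estimated correlation). Top2a rose by 3.23 (SE 0.43, 132 against 13.8 CPM), Mki67 by 3.10 (SE 0.42, 72.4 against 8.31 CPM), Birc5 by 2.67 (SE 0.35) and Tpx2 by 2.77 (SE 0.34). Of 27 effector markers 19 rose (22 over the list alone; 1.75, adjusted p = 5.79e-24, and adjusted p = 0.0616 with an estimated correlation), with Icos at 1.75 (SE 0.32) and Batf at 0.99 (SE 0.17), while Prdm1 was at 0.76 (SE 0.38, adjusted p = 0.29). Of 17 suppression genes 11 rose (13 over the list alone; 1.60, adjusted p = 1.97e-10, and adjusted p = 0.0828 with an estimated correlation), with Ctla4 at 1.01 (SE 0.23), Tigit at 2.59 (SE 0.65) and Lag3 at 2.76 (SE 0.49). Resting markers had 3 of 20 lower (7 over the list alone; -0.44, adjusted p = 9.78e-07, and adjusted p = 0.125 with an estimated correlation), with Lef1 at -0.71 (SE 0.17), Satb1 at -0.83 (SE 0.21) and S1pr1 at -0.93 (adjusted p = 0.0509, and 0.0321 with the replicate block).

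Helper and pathway lists of fl/fl moved at the preset correlation. Treg identity had 7 of 19 higher (list alone 10 and 1; 0.46, adjusted p = 5.51e-05, and adjusted p = 0.125 with an estimated correlation), and Ikzf2 was at 0.46 (adjusted p = 0.131, and 0.00882 with the replicate block). Th2 had 3 of 8 higher (1.54, adjusted p = 0.000286, and adjusted p = 0.0828 with an estimated correlation), with Ccr4 at 2.65 (SE 0.31) and Il1rl1 at 3.14 (SE 0.71). Th17 had 4 of 9 higher (7 over the list alone; 2.72, adjusted p = 9.25e-06, and adjusted p = 0.0862 with an estimated correlation), with Ccr6 at 2.72 (SE 0.51). Tfh had 4 of 10 higher (7 over the list alone; 1.03, adjusted p = 1.01e-06, and adjusted p = 0.0983 with an estimated correlation). Th1 had 7 of 16 higher (1.5, adjusted p = 1.52e-06, and adjusted p = 0.125 with an estimated correlation), with Cxcr3 at 3.45 (SE 0.56). Migration had 14 of 27 higher (list alone 15 and 3; 1.26, adjusted p = 1.58e-07, and adjusted p = 0.0763 with an estimated correlation), with Ccr2 at 3.04 (SE 0.68).

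Glycolysis had 7 of 21 genes higher in fl/fl (0.31, adjusted p = 2.22e-05, and adjusted p = 0.125 with an estimated correlation), and NF-kB targets 8 of 29 (list alone 10 and 2; 0.19, adjusted p = 0.0031, and adjusted p = 0.257 with an estimated correlation), with Tnfrsf9 at 0.74 (SE 0.22). CBM signalling (0 of 14; -0.16, adjusted p = 0.0389, and adjusted p = 0.131 with an estimated correlation) and the interferon list (1 of 26 lower; -0.19, adjusted p = 0.0259, and adjusted p = 0.69 with an estimated correlation) were lower. The other lists did not pass: early receptor response (-0.08, adjusted p = 0.753), apoptosis (-0.01, adjusted p = 0.596), oxidative phosphorylation (0.08, adjusted p = 0.234), cholesterol synthesis (0.16, adjusted p = 0.466), IL-2/STAT5 (-0.05, adjusted p = 0.997), dissociation (0.07, adjusted p = 0.974), B cells (-0.02, adjusted p = 0.53) and conventional CD4 cells (0.36, adjusted p = 0.175). Of the 674 genes 533 rose and 141 fell, and 662 rose and 54 fell on log2(FPKM + 1). With the block within genotype, chosen after seeing the data, which takes up the pairing of resting and effector libraries, 1071 genes were called. The count was 266 without fl/fl effector replicate 1, 321 without fl/fl resting replicate 2 and 292 without fl/fl resting replicate 3. Of 93 list members called in fl/fl, 42 stayed called whichever library was left out, Top2a, Mki67, Birc5, Tpx2, Lag3, Icos, Batf, Ccr4 and Cxcr3 among them. The other 51 did not, such as Ctla4, Tigit, Lef1, Satb1, Ccr2, Ccr6, Il1rl1 and Tnfrsf9. In +/+ 103 of 142 and in fl/+ 106 of 154 stayed called, and Ikzf2, Birc5 and Hmgcs1 in +/+ and Ifit1 and Rtp4 in fl/+ did not. NF-kB lost its call without fl/fl effector replicate 1 (0.11, adjusted p = 0.152). CBM signalling lost it without fl/fl effector replicate 1 (-0.13, adjusted p = 0.0792) or 3 (-0.14, adjusted p = 0.0776) and without resting replicate 2 (-0.17, adjusted p = 0.0561) or 3 (-0.14, adjusted p = 0.102). The interferon list lost it without fl/fl resting replicate 1 (-0.13, adjusted p = 0.241) or 2 (-0.07, adjusted p = 0.474) and without effector replicate 2 (-0.23, adjusted p = 0.0506) or 3 (-0.08, adjusted p = 0.489).

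Between fl/fl and +/+ effector cells the suppressive cytokine Il10 fell by 4.37 (SE 0.61, adjusted p = 0.00119), from 31.3 CPM (SD 10.2, n = 3) to 1.03 (SD 1.78, n = 3). Also lower were Lilrb4 (-2.72, SE 0.51), Arnt2 (-2.71, SE 0.55), Matn2 (-2.65, SE 0.43), Lrrfip2 (-2.32, SE 0.30, 6.81 against 34.7 CPM), Sccpdh (-2.30, SE 0.49), Dnahc7a (-2.27) and the syndecan Sdc4 (-2.21, SE 0.28, 22.8 against 112 CPM). Higher were Zan (3.66, SE 0.75), Rnf187 (2.86, SE 0.59), Ggt5 (2.76, SE 0.62), the phosphodiesterase Pde3b (2.63, SE 0.55, 14.0 against 1.99 CPM), the cyclase Adcy6 (2.52, SE 0.37, 18 against 2.97 CPM), Cnn3 (2.45, SE 0.37, 40.8 against 7.85 CPM), Faf1 (2.10) and Stt3b (1.36, SE 0.19).

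Genes of suppression and Treg identity were lower in fl/fl effector cells. Of 17 suppression genes 7 fell and 10 were not called (list alone 15 lower, 1 higher; median -1.31, adjusted p = 2.52e-16, 0.0279 with an estimated correlation). Ctla4 (-1.31, SE 0.22, adjusted p = 0.00425, 163 against 407 CPM), Lag3 (-2.16, SE 0.40, 80.6 against 366 CPM) and Havcr2 (-3.60, SE 0.66, 0.802 against 13.1 CPM) fell. Tigit was at -1.74 (SE 0.51, adjusted p = 0.0679, and 0.0106 with the replicate block), and Gzmb at -1.91 (SE 0.55, adjusted p = 0.0686, and 0.0372 with the replicate block). Of 19 identity genes 8 fell (10 over the list alone; -0.50, adjusted p = 1.09e-10, 0.0334 with an estimated correlation). They include Ikzf2 (-0.91, SE 0.17, adjusted p = 0.0078, 274 against 516 CPM), the ectoenzymes Entpd1 (-1.11, SE 0.23) and Nt5e (-0.92, SE 0.22), Capg (-0.76, SE 0.20) and Nrp1 (-0.82, SE 0.22). Foxp3 was at -0.18 (SE 0.24, adjusted p = 0.785, 287 against 325 CPM) and Il2ra at -0.09 (adjusted p = 0.83).

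Resting markers were higher in fl/fl effector cells, with 10 of 20 called higher (14 over the list alone; 0.79, adjusted p = 5.98e-17, 0.0279 with an estimated correlation). Lef1 rose by 1.06 (SE 0.18, adjusted p = 0.00425, 326 against 156 CPM), Satb1 by 1.27 (SE 0.23, 140 against 57.6 CPM), Klf2 by 1.69 (SE 0.39), S1pr1 by 1.28 (SE 0.29), Ccr7 by 0.68 (SE 0.17), Bach2 by 0.80 (SE 0.16) and Igfbp4 by 2.09 (SE 0.44). Effector markers had 4 of 27 lower (11 over the list alone; -0.54, adjusted p = 1.24e-08, and adjusted p = 0.133 with an estimated correlation): Icos (-1.15, SE 0.30, 225 against 509 CPM), Prdm1 (-1.78, SE 0.33, 17.0 against 62.6 CPM), Batf (-0.80, SE 0.15) and Maf (-1.62, SE 0.41) fell, and Klrg1 was at -0.22 (adjusted p = 0.938).

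Proliferation genes were higher in fl/fl than in +/+ effector cells. Of 28 genes 4 were called (21 over the list alone; 1.08, adjusted p = 2.65e-15, and adjusted p = 0.102 with an estimated correlation): Tpx2 (1.37, SE 0.30, 30.6 against 11.4 CPM), Stmn1 (1.19, SE 0.28), Birc5 (1.16, SE 0.31, 47.1 against 20.9 CPM) and Mcm2 (0.56, SE 0.12). Top2a was at 1.19 (SE 0.38, adjusted p = 0.0863) and Mki67 at 0.80 (adjusted p = 0.243). The summed level of the list was 1780 CPM in fl/fl, 1400 in fl/+ and 1130 in +/+ effector cells, and 590 to 632 CPM in the resting groups.

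NF-kB targets were lower as a set. Of 29 genes 2 fell (list alone 9 lower, 1 higher; -0.25, adjusted p = 2.18e-06, and adjusted p = 0.0958 with an estimated correlation): Tnfrsf1b (-1.16, SE 0.22) and Cd83 (-1.45, SE 0.38). Relb was at -0.57 (SE 0.17, adjusted p = 0.0693), Nfkb2 at -0.40 (adjusted p = 0.189) and Nfkbid at -0.55 (adjusted p = 0.0578, and 0.0257 with the replicate block). In the early receptor response 2 of 17 fell (list alone 3 lower, 2 higher; -0.05, adjusted p = 0.442), Nfatc1 (-0.78, SE 0.16) and Egr1 (-0.54, SE 0.14), and Egr2 was at -0.59 (adjusted p = 0.0655, and 0.0267 with the replicate block). CBM signalling had no call (list alone 2 and 2; -0.06, adjusted p = 0.919).

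Helper lists were lower as well in fl/fl effector cells. Th17 had 3 of 9 lower (5 over the list alone; -1.11, adjusted p = 5.38e-06, and adjusted p = 0.0738 with an estimated correlation), among them Ccr6 (-1.58, SE 0.37) and Ahr (-1.56, SE 0.40). Tfh had 3 of 10 lower (7 over the list alone; -0.87, adjusted p = 1.79e-05, and adjusted p = 0.105 with an estimated correlation), with Angptl2 (-1.57, SE 0.34), Sostdc1 (-4.17, SE 1.01) and Sh2d1a (-0.80, SE 0.18). Th2 had 1 of 8 lower (-0.44, adjusted p = 0.00787, and adjusted p = 0.105 with an estimated correlation) and Th1 0 of 16 (-0.26, adjusted p = 0.0128, and adjusted p = 0.408 with an estimated correlation), with Cxcr3 at -0.68 (adjusted p = 0.466). Of 27 migration genes 3 rose and 2 fell (list alone 6 and 11; -0.51, adjusted p = 0.00992, and adjusted p = 0.275 with an estimated correlation), with Gpr183 at -0.66 (SE 0.16) and Ccr2 at -1.74 (SE 0.48, adjusted p = 0.0535, and 0.0149 with the replicate block).

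Metabolic and other lists of fl/fl effector cells had few calls. Cholesterol synthesis (0 of 19; 0.36, adjusted p = 0.000229, and adjusted p = 0.175 with an estimated correlation) and oxidative phosphorylation (0 of 30; 0.10, adjusted p = 0.00546, and adjusted p = 0.396 with an estimated correlation) were higher as sets, with Hmgcs1 at 0.51 (adjusted p = 0.179). Glycolysis had Ldha higher (0.38, SE 0.10; list 0.04, adjusted p = 0.22), and apoptosis 2 of 23 higher (-0.15, adjusted p = 0.763), with Bcl2l11 at 0.74 (SE 0.18). IL-2/STAT5 had 1 of 19 higher (-0.02, adjusted p = 0.919). The interferon list was at -0.09 (adjusted p = 0.0686, and 0.0383 with the replicate block) and dissociation at 0.15 (1 of 21 lower, adjusted p = 0.959). Markers of conventional CD4 cells were higher, 4 of 7 called (0.44, adjusted p = 0.000365, 0.0279 with an estimated correlation), among them Itgb3 (1.26, SE 0.33) and Dgka (0.44, SE 0.10), and summed to 1890 CPM (SD 363) against 1160 (SD 225). B cell genes were at 0.87 (adjusted p = 0.919; 83.6 CPM against 86.8), and Prdm1 was the 1 gene called among plasma, myeloid, dendritic and CD8 or NK markers.

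**Figure D2:**
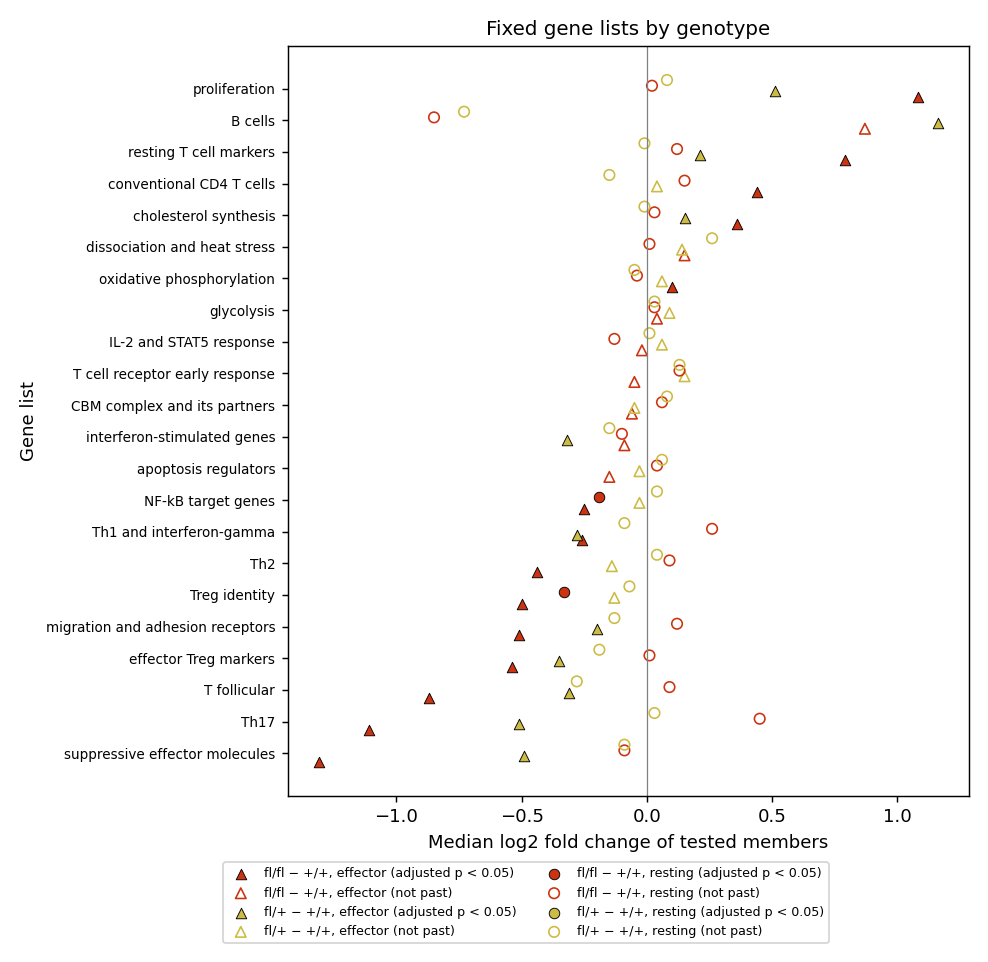
Median log2 change of the members of each tested list (horizontal) for fl/fl and fl/+ against +/+ in effector and in resting cells, filled where camera gave an adjusted p under 0.05. Suppression genes lie at -1.31 and resting markers at 0.79 in fl/fl effector cells.

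The fl/+ effector signature was shifted toward rest in fl/fl effector cells. Of its 200 genes higher in the effector state, 28 were above 0 in fl/fl against +/+, 67 were called lower and 4 higher (median -0.77, adjusted p = 1.95e-44, 0.0165 with an estimated correlation). Of its 200 genes lower in the effector state, 191 were above 0 and 57 were called higher (0.43, adjusted p = 1.56e-49, 0.0165 with an estimated correlation). In resting cells the medians were -0.10 (adjusted p = 0.00561, and adjusted p = 0.556 with an estimated correlation) and 0.09 (adjusted p = 0.000147, and adjusted p = 0.556 with an estimated correlation). The first did not hold in 4 of 6 leave-outs, where the camera value before adjustment was 0.0915 and 0.113 without +/+ resting replicates 1 and 2 (-0.07 and -0.06) and 0.276 and 0.823 without fl/fl resting replicates 2 and 3 (-0.07 and -0.02). Without fl/fl resting replicate 1 the median was -0.39, and without +/+ resting replicate 3 it was -0.18.

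Of the 299 genes called between fl/fl and +/+ effector cells, 124 were higher and 175 lower, 144 of them more than 2-fold. The replicate block gave 552 (244 and 308). Leave-outs gave 542 without +/+ effector replicate 3, 648 without fl/fl effector replicate 1, and 31, 51, 35 and 88 without +/+ effector replicates 1 and 2 and fl/fl effector replicates 2 and 3. Of 42 list members called, 2 stayed called whichever library was left out. Of 55 named genes, 9 did: Il10, Ctla4, Sdc4, Lrrfip2, Matn2, Ttn, Adcy6, Cnn3 and Amd2. For Amd2 summed with Amd1 the value was 0.01 (SE 0.11, adjusted p = 0.99). Without fl/fl effector replicate 2, Th1 (-0.12, adjusted p = 0.189), Th2 (-0.09, adjusted p = 0.062) and migration (-0.35, adjusted p = 0.0614) were not called. Nor was Th1 without fl/fl effector replicate 3 (-0.20, adjusted p = 0.208) or +/+ effector replicate 1 (-0.16, adjusted p = 0.0594). Of the higher genes with a protein-coding transcript, 43 of 118 (36.4%) held a GC-rich stretch (defined below), against 21% of all tested genes. Without all genes that hold one, 201 were called, 68 higher and 133 lower. The shares were not tested. A permutation test of the mean GC of the richest stretch, which takes genes as independent, gave the higher genes an adjusted p = 3e-04. Their median was 77%, against 72% over all tested genes. Of 12 sets tested, 2 departed the other way, each with a permutation adjusted p = 3e-04 for that mean. They were genes higher in effector than in resting cells of fl/fl (median 69%, with a GC-rich stretch in 63 of 504, 12.5%) and of fl/+ (71%, 177 of 969, 18.3%).

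**Figure D3:**
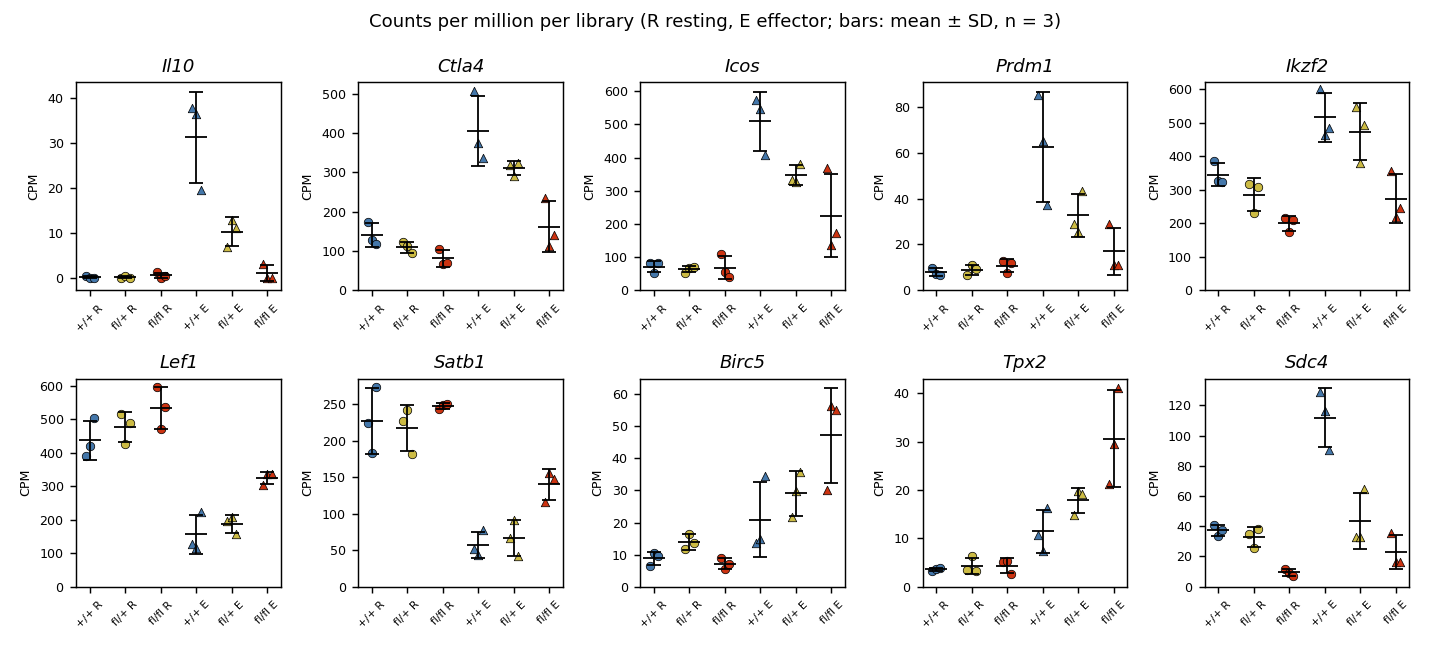
CPM of 10 genes in each library, by group, with mean and SD over 3 libraries. Il10 is at 31.3 CPM in +/+, 10.3 in fl/+ and 1.03 in fl/fl effector cells, and Tpx2 at 11.4 in +/+ and 30.6 in fl/fl.

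Between fl/fl and fl/+ effector cells, Il10 fell by 2.75 (SE 0.63, adjusted p = 0.0484, 1.03 against 10.3 CPM, SD 3.17, n = 3), with Lilrb4 (-2.39, SE 0.50), Matn2 (-2.12, SE 0.43), the interferon-induced Gbp1 (-1.86, SE 0.36, 17.0 against 57.8 CPM), Ahr (-1.80, SE 0.39), Lrrfip2 (-1.59) and Axl (-1.58, SE 0.35). Atp8b4 (2.91), Nedd4 (2.46, SE 0.52), Emid1 (2.18, SE 0.47), Vipr1 (1.78, SE 0.39), Gpr146 (1.60, SE 0.30), Adcy6 (1.55, SE 0.31, 18 against 6.05 CPM) and Cnn3 (1.53, SE 0.32) were higher. Resting markers had 4 of 20 higher (11 over the list alone; 0.49, adjusted p = 3.9e-14, and adjusted p = 0.0568 with an estimated correlation), among them S1pr1 (1.27, SE 0.28), Satb1 (1.06, SE 0.22) and Lef1 (0.79, SE 0.17). Treg identity had Ikzf2 lower (-0.78, SE 0.17; 1 of 19, list alone 13 lower and 1 higher; -0.51, adjusted p = 1.28e-09, and adjusted p = 0.0568 with an estimated correlation).

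Of the other lists in this contrast, suppression had 1 of 17 lower (list alone 7 and 1 higher; -0.91, adjusted p = 9.47e-09, and adjusted p = 0.0892 with an estimated correlation), and Ctla4 was at -0.92 (SE 0.22, adjusted p = 0.0618, and 0.00136 with the replicate block). Effector markers had no call (list alone 6 lower, 1 higher; -0.47, adjusted p = 5.79e-06, and adjusted p = 0.289 with an estimated correlation). NF-kB targets had none (9 lower over the list alone; -0.27, adjusted p = 2.33e-07, and adjusted p = 0.0876 with an estimated correlation), with Tnfrsf1b at -0.83 (adjusted p = 0.0782, and 0.0278 with the replicate block) and Nfkb2 at -0.58 (adjusted p = 0.0976, and 0.0448 with the replicate block). The early receptor response had Nfatc1 lower (-0.70, SE 0.16; list -0.34, adjusted p = 0.0193, and adjusted p = 0.289 with an estimated correlation). Th17 (-0.32, adjusted p = 0.000909, and adjusted p = 0.213 with an estimated correlation), Tfh (-0.60, adjusted p = 0.00267, and adjusted p = 0.289 with an estimated correlation) and Th2 (-0.29, adjusted p = 0.0293, and adjusted p = 0.239 with an estimated correlation) were lower.

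Proliferation genes were higher as a set (0 of 28 called; 0.45, adjusted p = 2.57e-05, and adjusted p = 0.43 with an estimated correlation). So were conventional CD4 markers (Itgb3 called of 7, at 1.39, SE 0.32; list 0.62, adjusted p = 0.0007, and adjusted p = 0.0555 with an estimated correlation, 1890 against 1220 CPM), the interferon list (0.26, adjusted p = 0.0451, and adjusted p = 0.661 with an estimated correlation) and cholesterol synthesis (0.19, adjusted p = 0.0428, and adjusted p = 0.552 with an estimated correlation). Th1 (0.07, adjusted p = 0.68) and migration (-0.32, adjusted p = 0.21) did not pass. The +/+ effector signature had 188 of 200 higher genes below 0, 19 of them called (median -0.66, adjusted p = 8.72e-54, 0.0157 with an estimated correlation), and 195 of 200 lower genes above 0, 28 of them called (0.37, adjusted p = 7.84e-59, 0.0157 with an estimated correlation). In fl/fl against fl/+ resting cells the higher genes had a median of 0.05 (adjusted p = 0.536), and the lower genes 0.05 (adjusted p = 0.0203, and adjusted p = 0.825 with an estimated correlation).

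The 72 genes called between fl/fl and fl/+ effector cells were 39 higher and 33 lower. On log2(FPKM + 1) 14 were higher and 19 lower, and on log2(FPKM + 0.1) 10 and 4. The replicate block gave 181, and leaving out fl/+ effector replicates 1, 2 and 3 gave 4, 171 and 3, and fl/fl effector replicates 1, 2 and 3 gave 310, 4 and 15. None of 25 named genes or 8 list members called stayed called without every library in turn. Without fl/fl effector replicate 2, Tfh (-0.35, adjusted p = 0.129), Th2 (-0.14, adjusted p = 0.377), the interferon list (0.22, adjusted p = 0.0694) and cholesterol synthesis (0.16, adjusted p = 0.0896) were not called. Th2 was lost too without fl/fl replicate 3 (0.06, adjusted p = 0.198) or fl/+ replicate 2 (-0.12, adjusted p = 0.104), and cholesterol synthesis without fl/fl replicate 1 (0.12, adjusted p = 0.157) or fl/+ replicate 3 (0.06, adjusted p = 0.386). The interferon list was lost without fl/fl replicate 1 (0.00, adjusted p = 0.943), fl/+ replicate 1 (0.09, adjusted p = 0.475) or fl/+ replicate 3 (0.23, adjusted p = 0.0952).

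Between fl/+ and +/+ effector cells 1 gene was called, Stt3b, a subunit of the oligosaccharyltransferase, which rose by 1.37 (SE 0.18, adjusted p = 0.00427, 81.2 against 32.0 CPM). It lost its call without +/+ effector replicate 1 and in the fit to only the groups compared. Il10 was at 10.3 against 31.3 CPM (-1.62, SE 0.47, adjusted p = 0.442), Gzmb at -1.72 (SE 0.53, adjusted p = 0.502), Ctla4 at -0.39 (adjusted p = 0.933), Top2a at 0.67 (adjusted p = 0.935) and Ifit1 at -0.41 (adjusted p = 0.953). No list member was called. As sets, suppression (-0.49, adjusted p = 8.12e-07; 2 lower over the list alone) and the interferon list (-0.32, adjusted p = 9.29e-08) were lower, and proliferation was higher (0.51, adjusted p = 1.71e-09). With an estimated correlation none of the 3 passed (adjusted p of 0.49 to 0.513), and at the preset correlation they passed whichever library was left out.

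A further 8 lists passed in that contrast at the preset correlation, but not with an estimated one (adjusted p of 0.49 to 0.513) nor without at least 1 library: effector markers (-0.35, adjusted p = 0.0176), Th1 (-0.28, adjusted p = 0.00563), Th17 (-0.51, adjusted p = 0.019), Tfh (-0.31, adjusted p = 0.019), migration (-0.20, adjusted p = 0.0373), resting markers (0.21, adjusted p = 0.011), cholesterol synthesis (0.15, adjusted p = 0.011) and B cells (1.16, adjusted p = 0.0428; 122 CPM, SD 47.1, against 86.8). Without fl/+ effector replicate 2, resting markers were at 0.07 (adjusted p = 0.798) and Tfh at -0.14 (adjusted p = 0.412). All 8 were lost without +/+ effector replicate 2, all but cholesterol synthesis without +/+ effector replicate 1, and all but Th1 without fl/+ effector replicate 2. Effector markers, Th17, cholesterol synthesis and migration were lost without fl/+ effector replicate 1, and B cells without replicate 3. At an unadjusted p under 0.05 there were 581 genes. The replicate block gave 34 genes (26 higher, 8 lower), DESeq2 21, log2(FPKM + 1) 1 higher and 1 lower, and leaving out +/+ effector replicate 3 or fl/+ effector replicate 1 gave 5.

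In resting cells, fl/fl against +/+ was led by genes of varied cell functions. The ubiquitin ligase Rnf187 rose by 3.50 (SE 0.62, adjusted p = 0.0105, 238 against 21.3 CPM), the phosphatase Ppm1d by 3.47 (SE 0.52, 16.5 against 1.53 CPM), Mrs2 by 2.67 (SE 0.45), Donson by 2.44 (SE 0.49), Ccny by 2.32 (SE 0.41), Glud1 by 2.23 (SE 0.36, 197 against 42.8 CPM), Aggf1 by 2.05 (SE 0.35), Tysnd1 by 1.95 (SE 0.35) and Stt3b by 1.54 (SE 0.19). Lower were Tgm2 (-2.31, SE 0.49), Fanci (-2.08, SE 0.46), Sdc4 (-1.99, SE 0.33, 9.46 against 37.4 CPM), Tns1 (-1.16, SE 0.23), Pou2f2 (-1.03, SE 0.16, 16.2 against 32.9 CPM), H2-Oa (-0.96), the NF-kB activating receptor Nod1 (-0.85, SE 0.16) and Cd274 (-0.69, SE 0.16).

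Treg identity was lower in fl/fl resting cells, with 2 of 19 called lower (5 over the list alone; -0.33, adjusted p = 6.46e-08, and adjusted p = 0.276 with an estimated correlation): Ikzf2 (-0.79, SE 0.17, 200 against 346 CPM) and Entpd1 (-1.12, SE 0.25, 15.7 against 33.9 CPM). Ctla4 was at -0.79 (SE 0.23, adjusted p = 0.171, and 0.00544 with the replicate block), and Foxp3 at -0.20 (adjusted p = 0.914). NF-kB targets had no call (-0.19, adjusted p = 0.00236, and adjusted p = 0.973 with an estimated correlation), with Nfkbia at -0.41 (SE 0.16, adjusted p = 0.46). Klf3 rose (0.77, SE 0.17) in the resting markers (0.12, adjusted p = 0.305). No other list passed, among them CBM signalling (0.06, adjusted p = 0.908), suppression (1 of 17 lower; -0.09, adjusted p = 0.31), effector markers (0.01, adjusted p = 0.908), early receptor response (0.13, adjusted p = 0.31), interferon (-0.10, adjusted p = 0.143), proliferation (0.02, adjusted p = 0.777) and migration (0.12, adjusted p = 0.908).

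The 74 genes of that contrast were 58 higher and 16 lower, and 179 with the replicate block (144 and 35). The count was 6, 13 and 154 without +/+ resting replicates 1, 2 and 3, and 26 and 11 without fl/fl resting replicates 2 and 3. Of 21 named genes and 3 list members called, Pou2f2 alone stayed called whichever library was left out. The NF-kB list was not called without +/+ resting replicate 1 (-0.17, adjusted p = 0.0672). Of the higher genes with a protein-coding transcript, 49 of 53 (92.5%) held a stretch of 100 bases with at least 80% G and C, against 1984 of 9610 (20.6%) of the other tested genes. Without all genes that hold one, a test chosen after seeing the data, 9 were called.

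**Figure D4:**
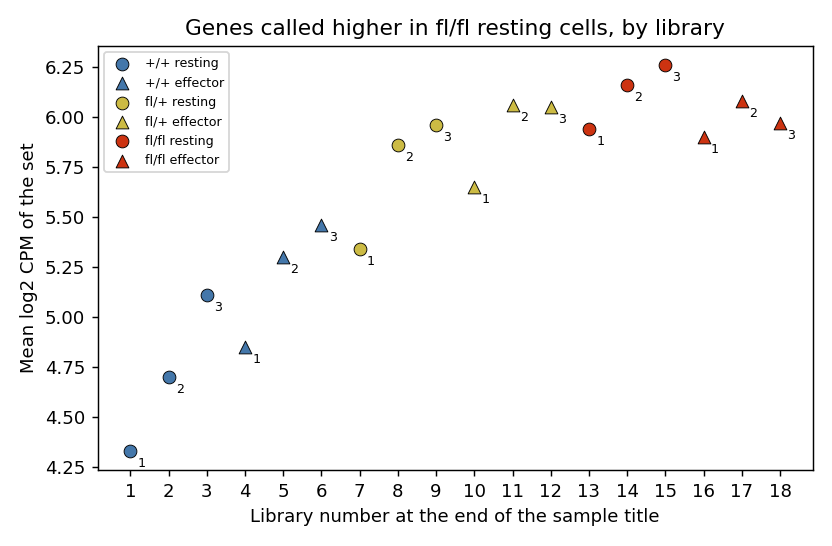
Mean log2 CPM of the 58 genes called higher in fl/fl than in +/+ resting cells (vertical) in each library, by the library number in its title (horizontal), with groups in colour. Levels run from 4.33 to 5.11 in +/+ resting and from 5.94 to 6.26 in fl/fl resting libraries.

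Between fl/+ and +/+ resting cells 9 genes were called, 6 higher and 3 lower. Stt3b rose by 1.42 (SE 0.19, adjusted p = 0.00115, 79.9 against 30.1 CPM), Tysnd1 by 1.88 (SE 0.35), the Notch regulator Dtx1 by 1.27 (SE 0.20, 136 against 56.8 CPM) and Zfp592 by 0.75 (SE 0.12). The decarboxylase gene Amd1 had no count in fl/+ and 105 CPM in +/+, and Amd2 had 99.5 CPM in fl/+ and no count in +/+. The others were Gm13363, Gm10033 and 8430419L09Rik. No list member was called and no list passed. The nearest were the early receptor response (0.13), the interferon list (-0.15), each with an adjusted p of 0.0504, and dissociation (0.26, adjusted p = 0.0651), and each was at 0.0336 with the replicate block. Within them Egr1 was at 0.26 (SE 0.14, adjusted p = 0.867) and Hspa1b at 1.96 (SE 1.17, adjusted p = 0.894).

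The replicate block gave 90 genes in that contrast (79 higher, 11 lower). Leaving out +/+ resting replicates 1, 2 and 3 gave 3, 4 and 75 genes, and fl/+ resting replicates 1, 2 and 3 gave 19, 5 and 3. Stt3b stayed called whichever library was left out. So did Amd1 and Amd2, whose summed counts were not called (-0.08, SE 0.11, adjusted p = 0.971).

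Between fl/fl and fl/+ resting cells 3 genes were called: Amd1 (85.7 CPM against no count), Amd2 (0.0994 against 99.5 CPM) and 8430419L09Rik. The summed counts of Amd1 and Amd2 were at -0.22 (SE 0.11, adjusted p = 0.995). NF-kB targets (-0.21, adjusted p = 6.3e-08, and adjusted p = 0.247 with an estimated correlation) and Treg identity (-0.23, adjusted p = 4.04e-06, and adjusted p = 0.247 with an estimated correlation) were lower as sets, with no member called. The dissociation list was lower (-0.18, adjusted p = 0.0232, and adjusted p = 0.987 with an estimated correlation), and was at 0.07 without fl/+ resting replicate 1 (adjusted p = 0.526), at -0.18 without fl/fl resting replicate 1 (adjusted p = 0.132) and at -0.13 without fl/fl resting replicate 3 (adjusted p = 0.253).

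The interaction for fl/fl asks whether the change between states differs from that in +/+. No gene passed with edgeR, where 953 were under an unadjusted p of 0.05. The replicate block gave 3, DESeq2 15, log2(FPKM + 1) 5 and log2(FPKM + 0.1) 0, and leaving out +/+ effector replicate 3 or fl/fl effector replicate 1 gave 15 and 33. As sets, resting markers fell less in fl/fl (median 0.86, adjusted p = 7.15e-11, and adjusted p = 0.205 with an estimated correlation; 10 higher over the list alone), and proliferation rose more (0.80, adjusted p = 3.26e-12, and adjusted p = 0.23 with an estimated correlation; 4 higher over the list alone). Suppression (-0.96, adjusted p = 1.24e-06) and Th2 (-0.53, adjusted p = 0.018), Th17 (-1.95, adjusted p = 0.00256) and Tfh (-0.87, adjusted p = 0.000204) genes rose less, each with an adjusted p of 0.23 with an estimated correlation. Effector markers (-0.79, adjusted p = 1.24e-06, and adjusted p = 0.269 with an estimated correlation) and Th1 genes (-0.46, adjusted p = 0.00471, and adjusted p = 0.351 with an estimated correlation) rose less too.

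Oxidative phosphorylation (0.15, adjusted p = 0.00242), cholesterol synthesis (0.26, adjusted p = 0.00886) and conventional CD4 markers (0.33, adjusted p = 0.018) were higher in the fl/fl interaction, with adjusted p = 0.351, 0.351 and 0.205 with an estimated correlation. The early receptor response was at -0.09 (adjusted p = 0.0502, and 0.0416 with the replicate block), NF-kB targets at -0.12 (adjusted p = 0.0865) and Treg identity at -0.08 (adjusted p = 0.0865). Without fl/fl resting replicate 1, effector markers were at -0.07 (adjusted p = 0.0575), Th1 at 0.16 (adjusted p = 0.192), Th2 at -0.03 (adjusted p = 0.332), Th17 at -0.63 (adjusted p = 0.083), Tfh at -0.45 (adjusted p = 0.0575) and oxidative phosphorylation at 0.12 (adjusted p = 0.0575). Without fl/fl effector replicate 2, Th1 was at -0.22 (adjusted p = 0.0626) and Th2 at -0.30 (adjusted p = 0.11). Th2 was also lost without +/+ effector replicate 1 (-0.51, adjusted p = 0.0555) and +/+ resting replicates 2 (-0.30, adjusted p = 0.0553) and 3 (-0.29, adjusted p = 0.0695). Conventional CD4 markers were lost without +/+ resting replicate 3 (0.30, adjusted p = 0.096), fl/fl resting replicate 2 (0.29, adjusted p = 0.0619) or 3 (0.36, adjusted p = 0.0554). Cholesterol synthesis was at 0.22 without fl/fl resting replicate 3 (adjusted p = 0.0624).

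With the block within genotype, chosen after seeing the data, 120 genes passed in the fl/fl interaction, 29 higher and 91 lower. Lower were Il10 (-6.73, SE 1.38, adjusted p = 0.0217), Gzmb (-4.53, SE 0.95), Ccr2 (-3.26, SE 0.60), Tigit (-2.75, SE 0.31), Prdm1 (-2.29, SE 0.36), Lag3 (-2.01, SE 0.40), Icos (-1.10, SE 0.21) and Malt1 (-1.01, SE 0.21, adjusted p = 0.0217). Higher were Top2a (2.14, SE 0.49), Igfbp4 (2.13, SE 0.46), Satb1 (1.16, SE 0.17), Bach2 (0.96, SE 0.17), Lef1 (0.81, SE 0.17) and Ccr7 (0.71, SE 0.16).

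The interaction for fl/+ called Amd1 and Amd2, which were each near or at no count in part of the groups, and 343 genes were under an unadjusted p of 0.05. Proliferation genes rose more in fl/+ (0.36, adjusted p = 0.000113, and adjusted p = 0.898 with an estimated correlation), but not without +/+ effector replicate 1 (0.15, adjusted p = 0.151). Oxidative phosphorylation was higher (0.13, adjusted p = 0.00949, and adjusted p = 0.898 with an estimated correlation) and was lost without +/+ resting replicate 1 (0.12, adjusted p = 0.0581) or 2 (0.11, adjusted p = 0.0604), +/+ effector replicate 1 (0.12, adjusted p = 0.151) or fl/+ effector replicate 2 (0.07, adjusted p = 0.153). Suppression, effector markers, resting markers and all other lists did not pass.

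Changes of fl/+ and fl/fl against +/+ use the same +/+ libraries. Across tested genes their correlation was 0.516 in resting cells (Spearman rho 0.518, covariance 0.129) and 0.582 in effector cells (rho 0.519, covariance 0.124). In 50 simulations with no genotype effect, sharing alone gave a mean correlation of 0.512 in resting cells (0.457 to 0.561, 25 at least as high as the real one, covariance 0.0694) and 0.518 in effector cells (0.467 to 0.549, 0 as high, covariance 0.0534). The real covariance was above every simulation in both states (highest 0.0803 and 0.0587), while the correlation was so in effector cells alone. Without fl/+ effector replicate 2 the effector correlation was 0.458, under the lowest simulation, though no simulation left that library out. A shared change therefore stays open in both states. The simulations draw each gene on its own and hold no structure shared between genes. The +/+ libraries were too few to divide between both contrasts, and genes are not independent replicates. Stt3b and Tysnd1 were among 5 genes called higher in both resting contrasts, of 6 and 58 (a mean of 0.02 in the simulations), and no gene was called lower in both (of 3 and 16). In effector cells 1 of 1 and 124 was shared higher, Stt3b (a mean of 0 in the simulations). These shared genes all belong to the 58, of which 92.5% of those with a protein-coding transcript held a GC-rich stretch. Of the 58, 57 were above 0 in fl/+ against +/+ resting cells (median 0.91), and 57 in effector cells (0.65). The simulations hold no such pattern, so the overlap cannot tell a genotype effect from one that follows library number.

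Changes of fl/fl against +/+ in resting and effector cells had a correlation of 0.258 (Spearman rho 0.182, covariance 0.0703), and of 0.151 without +/+ resting replicate 1. Of 58 and 124 genes called higher, 17 were shared, Rnf187 and Stt3b among them. These 17 are part of the 58 genes of which 92.5% held a GC-rich stretch, and 53 of the 58 were above 0 in effector cells. Of 16 and 175 called lower, 7 were shared, among them Sdc4, Ikzf2 and Entpd1. Resting and effector libraries of one genotype and number deviate together (mean correlation of residuals 0.25), so the contrasts are not independent. What this pairing alone would give was not simulated, and a change common to both states stays open.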

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

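The tests of explanations below were written after the results were seen, except the rho test of GC-rich stretches and the splits of libraries, which were set before their values were known. A result is listed here when the interaction test showed a difference between genotypes in the change from resting to effector cells.

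In the interaction for fl/fl, 11 lists passed. Their median log2 values were -0.96 for suppression, -0.79 for effector markers, 0.86 for resting markers, -0.46 for Th1, -0.53 for Th2, -1.95 for Th17, -0.87 for Tfh, 0.80 for proliferation, 0.15 for oxidative phosphorylation, 0.26 for cholesterol synthesis and 0.33 for conventional CD4 markers. In the interaction for fl/+, proliferation was at 0.36 and oxidative phosphorylation at 0.13. The genes listed were Amd2, with a fitted value of -15.66, and Amd1, with 12.31, each fitted against groups with no count. No list of the interactions passed with an estimated correlation.

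Effector cells of fl/fl lay nearer to resting cells than +/+ effector cells did. Resting cells in the fl/fl effector gate might give lower suppression genes and higher Lef1 and Satb1, but would also lower proliferation. Summed proliferation was 1.58 times that of +/+ (1520 to 1920 against 922 to 1480 CPM), which argues against such cells as the whole cause. The +/+ effector libraries standing apart could give the same contrast, but the +/+ effector signature was also lower in fl/fl against fl/+ effector cells, with a median of -0.66, which argues against that. Conventional CD4 markers were higher too (median 0.44, 1890 against 1160 CPM). They summed to 2140 to 2290 CPM in resting groups, so they cannot tell conventional cells from a shift toward rest. Lower expression of part of the effector programme with more cycling cells could give the pattern. A change in the mix of sorted cells stays open, as neither sorted fractions nor protein were measured.

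Of the 58 genes higher in fl/fl than in +/+ resting cells, 49 of 53 held a GC-rich stretch. The GC of the richest stretch had a median of 82% against 72% for the other genes. A permutation test of its mean gave p = 1e-04, the smallest possible with 10000 resamples, and adjusted p = 3e-04 over 12 sets. Whole transcripts of the set had a median of 50.8% against 49.7%, which argues against overall GC content as what sets these genes apart, though the change from number 1 to 3 across genes followed it with rho 0.133 in +/+ effector cells and 0.211 and 0.23 in fl/+ and fl/fl resting cells. Replicate 1 was lowest for the set in 6 of 6 groups (exact p = 0.00412 over 729 arrangements). That p takes the 6 groups as independent, but resting and effector libraries of one genotype and number deviate together, so it is too low. The +/+ and fl/fl resting groups also chose the set. Since every group holds each number once, the order of the numbers decides nothing about genotype, which stays open. Low recovery of GC-rich stretches in some libraries could give the pattern, and its test stayed open: across 6223 genes of +/+ effector cells rho was 0.087, between the bounds of 0.05 and 0.1. It was 0.202 in +/+ resting cells, which chose the set, and 0.191 there without the set. It was 0.062 and 0.007 in fl/+ and 0.093 and 0.013 in fl/fl resting and effector cells. Transcript length also went with the change from number 1 to 3, with rho 0.187 in +/+ resting cells and -0.247 to -0.118 in the other groups. Low recovery cannot be told apart from genotype here, because the library numbers in the titles follow genotype.

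Amd1 and Amd2 were called in opposite directions. Reads that fit both near-identical copies could be given to either one by the quantification, and their summed counts had an interaction of -0.02 (SE 0.15), with a sum of 85.8 to 105 CPM in every group. This is consistent with assignment of shared reads and with no change in the sum.

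Each contrast was also fitted to the 10 ways of dividing its 6 libraries 3 against 3, the real one included, and 10 splits are too few for a share under 0.05. The real division called the most genes, 1 of 10, in effector against resting cells of +/+ (1700, highest other 0), fl/+ (1732, highest other 0) and fl/fl (674, highest other 2), in fl/fl against +/+ resting cells (74, highest other 1) and effector cells (299, highest other 2), in fl/+ against +/+ resting cells (9, highest other 0), and in fl/fl against fl/+ resting cells (3, highest other 0) and effector cells (72, highest other 9). For fl/+ against +/+ effector cells 2 of 10 called as many (1, highest other 1). For the fl/fl interaction the real count was 0, which all 50 divisions reach by definition, so the comparison decides nothing, and the 49 random ones called up to 73. For fl/+ 4 of 50, the real division and 3 random ones, reached the real 2, with up to 66. In the splits with 73 and 66 all effector libraries of both genotypes changed places while most or all resting ones did not, so the genotype difference itself enters these counts. A split for fl/+ that mixed genotypes in both states called 38, which points to some structure among the samples, and what it is was not tested.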

How the results depend on the processing

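Of 337 gene results, 186 lost their call in at least 1 alternative or leave-out and 0 turned direction. Of 96 called lists, 19 kept their call with an estimated correlation and 77 did not, 42 lost it with fry, and 4 turned direction in camera without some library. Tests chosen after seeing the data are named so above.

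With no filter, which tests more genes, the counts were 1012 for effector against resting in fl/fl, 315 for fl/fl against +/+, 219 for fl/+ against +/+ and 94 for fl/fl against fl/+ in resting cells, 830, 176 and 488 for the same contrasts in effector cells, and 246 and 31 for the interactions of fl/fl and fl/+. The cause was not tested. A fit to only the groups compared, which has fewer libraries for the dispersion, gave 349 between states in fl/fl, then 35, 5 and 6 in resting and 154, 0 and 4 in effector cells in that order.

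The replicate block gave 179 for fl/fl and 90 for fl/+ against +/+ in resting cells, 552 and 34 in effector cells, 181 for fl/fl against fl/+ effector cells and 3 for the fl/fl interaction. It changed no other call of a gene or list valued in the report than those printed there with it. The block within genotype gave 1071 between states in fl/fl and 120 in the fl/fl interaction. Neither cause was tested.

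DESeq2 gave 129 for fl/fl and 39 for fl/+ against +/+ in resting cells, 21 for fl/+ against +/+ and 182 for fl/fl against fl/+ in effector cells, and 15 for the fl/fl interaction. On log2(FPKM + 1) the counts were 2 for fl/+ against +/+ and 33 for fl/fl against fl/+ in effector cells and 5 for the fl/fl interaction, and on log2(FPKM + 0.1) 183 for fl/fl against +/+ and 14 for fl/fl against fl/+ effector cells. The cause was not tested. The median of all genes was between -0.01 and 0.09 under every scaling. RLE and the stricter filter left every count within 1.5 times.

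Without genes that differ between replicate numbers, fl/+ against +/+ effector cells had 3 calls. Without genes holding a GC-rich stretch, fl/fl against +/+ resting cells had 9, fl/fl against +/+ effector cells 201, fl/+ against +/+ resting cells 4 and fl/+ against +/+ effector cells 0, in each case with fewer genes tested. The effector signature in fl/fl resting cells was at -0.101 and 0.09 with an estimated correlation, no longer past the threshold.

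Leaving out libraries, singly or all of one number, leaves fewer samples. The counts then ran from 821 to 1589 between states in +/+, 855 to 1601 in fl/+ and 184 to 791 in fl/fl. In resting cells they ran from 1 to 154 for fl/fl against +/+, 3 to 75 for fl/+ against +/+ and 1 to 6 for fl/fl against fl/+, and in effector cells from 7 to 648, 1 to 9 and 1 to 310. The interactions ran from 0 to 33 for fl/fl and 1 to 2 for fl/+. The lowest values for fl/fl against +/+ came without every library of replicate 2, with 1 in resting and 7 in effector cells.

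Values that crossed 0 when libraries were left out were dissociation in fl/fl against fl/+ resting cells (-0.422 to 0.127, and 0.072 without fl/+ resting replicate 1), resting markers (-0.061 to 0.659) and Tfh genes (-0.735 to 0.042) in fl/+ against +/+ effector cells, and interferon genes in fl/fl against fl/+ effector cells (-0.025 to 0.381). With the camera direction kept, the median also crossed 0 for Th1 genes in the fl/fl interaction (0.161), Th2 genes in fl/fl against fl/+ effector cells (0.063) and cholesterol synthesis in fl/+ against +/+ effector cells (just under 0). The 200 higher signature genes in fl/fl resting cells ran from -0.394, without fl/fl resting replicate 1, to -0.017. The correlation of fl/+ and fl/fl changes ran from 0.435 to 0.651 in resting and 0.458 to 0.714 in effector cells, and that of fl/fl changes in both states from 0.151 to 0.269. The cause was not tested.

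With a median of 3154386.5 expected counts per library, a gene at 1 CPM had about 3 counts, so genes such as Gzmb and Il10 were near the floor in resting cells, and 80 list genes could not be tested.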

Other observations

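Among genes of costimulation and metabolism in +/+ cells, Cd40lg rose with the effector state by 0.57 (adjusted p = 0.0287), and Casp8 fell by 0.61 (SE 0.12, adjusted p = 0.00201). Dgka, an enzyme that dampens receptor signals, fell by 0.65 (SE 0.10) in +/+ and was higher in fl/fl than in +/+ effector cells (0.44, SE 0.10, adjusted p = 0.0289). Myc fell by 0.77 (SE 0.17, adjusted p = 0.00418) in +/+, and Bcl2 was higher in fl/fl effector cells (0.78, SE 0.19, adjusted p = 0.0364). Xist rose by 0.37 (SE 0.11, adjusted p = 0.0213) in fl/+ effector cells.

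Between replicate numbers, 175 genes differed in the fit with the replicate block. A separate test of number 3 against number 1 called 124 higher and 74 lower. Ribosomal protein genes took 9.88 to 13.9% of each library.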
